A study of Danio rerio with 9 samples.

How the data were processed

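Total RNA was extracted from dissected embryonic eyes, labelled with biotin and hybridized to Affymetrix zebrafish arrays, per the labels' protocols. There was 1 array for each of 9 samples: untreated eyes at 24 hpf, and control and ethanol eyes at 27, 30, 36 and 48 hpf. The dose and timing of ethanol are not given in the sources used here. The deposited values are MAS5 signal intensities on a linear scale, named as MAS5 per the submitters' processing notes, with its version not given in the sources used here. The mean signal after trimming 2% at each end was about 125 on every array, so the arrays had been scaled to a common level before deposit and were used as deposited. MAS5 subtracts mismatch probes, so dim probe sets are noisy. The deposited tables used here hold no detection calls, and no depth or counting interval exists for array signals.

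Groups followed the sample titles, with which the source names matched for all 9 samples. The treatment characteristic contradicted both for 3 samples: the 30 hpf ethanol and 36 hpf ethanol arrays were marked as untreated and the 36 hpf control as ethanol. That characteristic was run as an alternative label, as was a fit on the 27 and 48 hpf pairs alone.

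Of 15617 probe sets, 115 spike and control probe sets were left out. Signals became log2(signal + 5), where 5 is the 20th percentile of all values rounded to a whole number. The upper 60% by mean log2 value over the 9 arrays was kept, which is 9301 probe sets with a mean signal above about 22.7. In the platform annotation, 10802 probe sets had 1 gene symbol, 135 had several and 4680 had none given, and 10718 symbols were looked up by their gene identifiers. Of the kept probe sets, 2180 had no single symbol and were tested without being named. The brightest probe set stood for each of 6111 genes. No genome coordinates were used.

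All fits used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with Benjamini-Hochberg adjustment at 0.05). The ethanol effect was fitted on the 8 paired arrays with stage as a block, which leaves 3 residual degrees of freedom and asks for a difference shared by the 4 stages. Development was the slope on hpf over 9 arrays with ethanol as a term, given as the change over 24 hours, and a call also needed at least a 2-fold change. The interaction was the product of hpf and ethanol over 9 arrays. At each stage the 2 arrays gave values only, counted when at least 2-fold apart with the brighter array above its median. The standard errors come from limma's moderated variances.

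Gene lists numbered 31: heat shock and HSF1 genes, heat shock transcription factors alone, ER stress, oxidative stress, alcohol and aldehyde metabolism, p53 and apoptosis, immediate early genes, hypoxia and glycolysis, cholesterol synthesis, retinoic acid, Hedgehog, Wnt, Fgf and Notch pathways, cell cycle, retinal progenitor, retinal ganglion cell, photoreceptor and inner retina genes, lens crystallins, lens membrane and regulators, pigment cells, optic stalk and periocular genes, muscle, blood and vessels, skin and hatching gland, cartilage and connective tissue, brain genes outside the eye, circadian clock, ribosomal proteins and mitochondrial respiration. Of these, 29 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 and, beside it, an estimated correlation. With an estimated correlation, camera also takes its reference distribution from the few residual degrees of freedom of the fit. A call lost under that setting is therefore not an effect of correlation alone. In fry, the p-value reported asks whether a list's genes move on balance in one direction, and neither it nor its mixed form compares the list with other genes. The ribosomal pattern also took in kinases such as rps6kb1b and rps6ka3a, and the mitochondrial pattern took in assembly factors. At each stage a list's median was placed among 10000 random lists of the same size matched on mean signal in 20 bins.

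The genes named were those with 1 symbol that was not a clone or locus name. They were the 10 called genes with the largest mean change in each direction for ethanol, the 5 largest changes in each direction at each stage, the 10 steepest called genes in each direction for development, and up to 5 genes of smallest p in each direction for the interaction. To these came the 4 members of each list with the largest mean ethanol difference, the 3 steepest called members for development, and the heat shock factors. The genes phlda3, hes6, pdia4 and pdia6, those of the plotted panels outside the rule and those in the closing section outside it were chosen after their values were seen.

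Each ethanol array was placed on the path of the controls by least squares over the 500 kept probe sets with the largest variance among the controls, and the error came from placing the 27, 30 and 36 hpf controls on the path of the others.

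Groups, tests, lists, the naming rule and a set of alternatives were fixed before the data were examined. The alternatives were the offset, quantile or median scaling, the filter, the 2 other labels, the stage term, the variance prior, the time scale, the arrays in each fit, the correlation and probe sets in list tests, the fold threshold, the probe sets on the path, and each stage left out in turn. The level of the brain list as a covariate and the removal of genes in other-tissue lists (also for the placement on the path) were added later, as were 8 gene lists: yolk and liver, heart, forebrain, midbrain, hindbrain, nucleolar and ribosome assembly, glycine, serine and one-carbon metabolism, and inflammation and acute stress. The lists removed were brain genes outside the eye, muscle, blood and vessels, skin and hatching gland, cartilage and connective tissue, yolk and liver, and heart. The forebrain, midbrain and hindbrain lists were not among them, so brain genes such as olig3 stayed in.

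The procedure was tested on simulated data with 9301 probe sets and 50 changed probe sets of each size. For ethanol, it recovered 12%, 90%, 98% and 100% of changes of 0.5, 1, 2 and 3 on the log2 scale, with 6 false calls. For development the shares were 10%, 74%, 98% and 98% with 5 false calls. For the interaction they were 0%, 8%, 62% and 88% with 1 false call. Data with no change gave 0 calls in each. The simulated noise was independent between probe sets, so differences shared by many genes of an array were not part of it. The numbers of false calls need not hold for the real arrays.

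The arrays differed in technical measures. The geometric mean of the spike controls ran from 645 to 946, with ethanol minus control differences of -0.15, -0.28, 0.45 and 0.27 (log2) at 27, 30, 36 and 48 hpf, and the GAPDH ratio of 3' to 5' signal ran from 1.83 to 2.67.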

Results

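Gene expression was measured in eyes dissected from zebrafish embryos, with and without exposure to ethanol, on 9 Affymetrix microarrays with 1 array per condition. An untreated sample was taken at 24 hours post fertilization (hpf). Control and ethanol samples followed at 27, 30, 36 and 48 hpf, a period in which the optic cup passes from dividing progenitors to the earliest neurons and lens fibres. The title of the study names Heat Shock Factor 1, a transcription factor that switches on chaperone genes under protein stress. The values were MAS5 signals (a brightness per probe set), scaled so that the mean after trimming 2% at each end was about 125 on every array. The number of arrays limits the precision. With no replicates, the spread behind each test came from the 4 stages or from the distance to a fitted line, so p-values measured only the spread between these samples, part of which may be technical. Of 15617 probe sets, 9301 were bright enough to be tested, and they covered 6111 named genes. Differences are given as log2(signal + 5), which understates the change of dim genes.

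Across the 4 stages, the genes with the largest rise in ethanol-exposed eyes included slc16a9b, slc16a9a, abat and gcshb, and the gene with the largest fall was h2ax. The gene slc16a9b, of the monocarboxylate transporter family, was higher by 2.51 ± 0.12 (log2, SE over 4 stages; adjusted p = 1.17e-04), with signals of 29.5 in the control and 212 in the ethanol array at 27 hpf and 40.1 and 236 at 48 hpf. Its paralog slc16a9a was higher by 2.21 ± 0.23 (adjusted p = 0.00671), and its difference was 1.41 at 27 hpf and 3.02 at 48 hpf. The gene abat, which encodes the transaminase that degrades the transmitter GABA, was higher by 1.87 ± 0.13 (adjusted p = 8.26e-04). The gene gcshb, for the H protein of the mitochondrial glycine cleavage system, was higher by 1.72 ± 0.15 (adjusted p = 0.00403). Among genes that were lower, h2ax, the histone variant phosphorylated at DNA breaks, fell by 1.22 (SE 0.13, adjusted p = 0.00671), and its signal at 27 hpf was 439 in the control against 188 with ethanol.

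**Figure D1:**
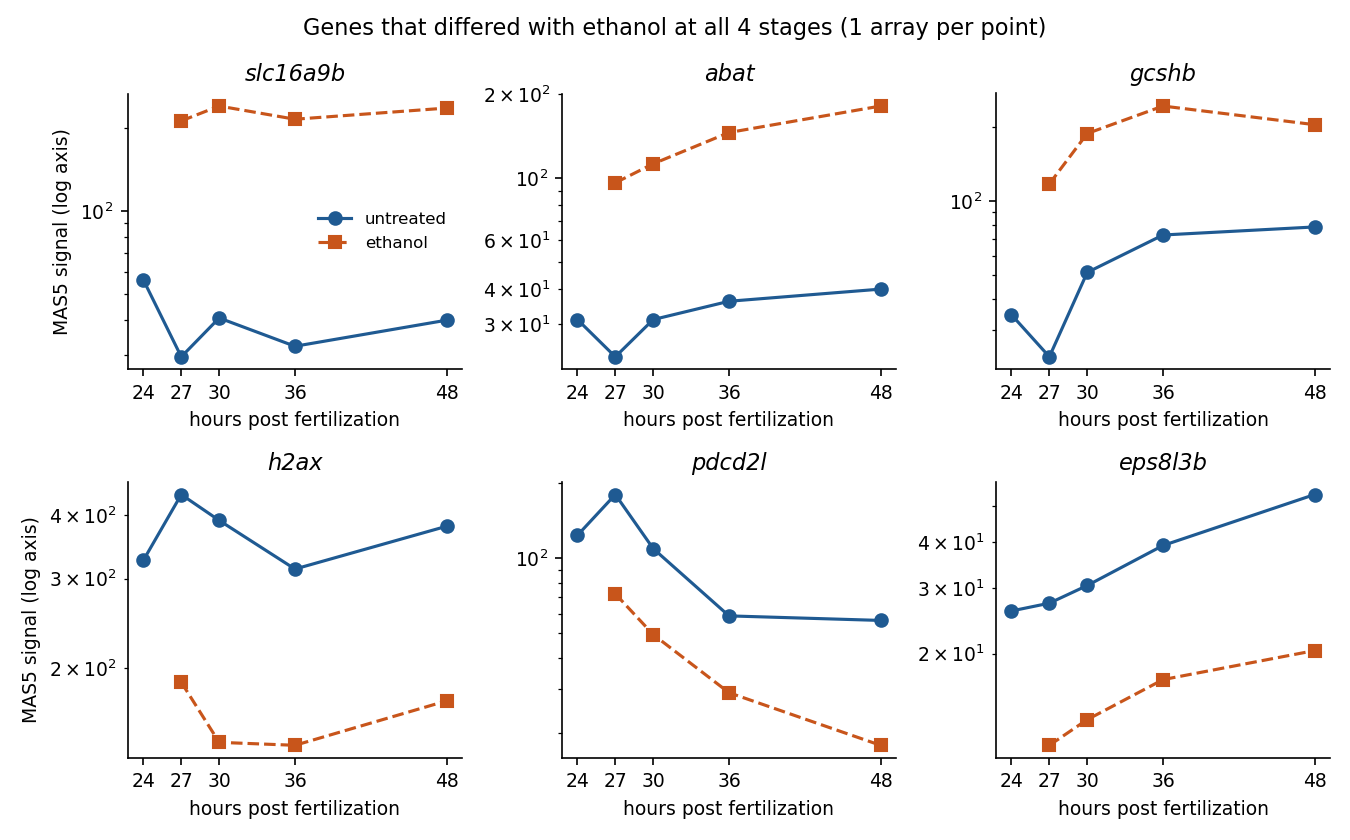
MAS5 signal (log axis) against hours post fertilization for 6 genes that differed with ethanol, with untreated eyes as circles and ethanol-exposed eyes as squares, 1 array per point. The ethanol array lies above the untreated array at all 4 stages for slc16a9b, abat and gcshb, and below it at all 4 stages for h2ax, pdcd2l and eps8l3b.

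Markers of tissues beside the eye were among the other genes that were higher. They included the engrailed genes of the midbrain-hindbrain boundary, en1b (1.76 ± 0.35, adjusted p = 0.0449) and en2a (1.65 ± 0.30, adjusted p = 0.0414), and olig3, a transcription factor of the dorsal hindbrain (1.55 ± 0.29, adjusted p = 0.0414). Further ones were fetub, a protease inhibitor secreted by the liver (1.70 ± 0.32, adjusted p = 0.0423), and fabp1b.1, a liver and gut fatty acid-binding protein (1.58 ± 0.26, adjusted p = 0.0307). The cytokine-responsive kinase gene pim2 was higher by 1.68 ± 0.32 (adjusted p = 0.0428), with a difference of 0.98 at 27 hpf and 3.14 at 48 hpf. The genes that were lower included pdcd2l, linked to assembly of the small ribosomal subunit (-1.17 ± 0.14, adjusted p = 0.0112), eps8l3b, of a family of actin regulators (-1.04 ± 0.12, adjusted p = 0.0112), and surf6, a nucleolar protein of ribosome assembly (-0.97 ± 0.14, adjusted p = 0.0262). The genes called lower also included slc25a25a, an adenine nucleotide carrier (-0.95 ± 0.17), micos10, a subunit of the complex that shapes cristae (-0.94 ± 0.13), mrps28, a mitochondrial ribosomal protein (-0.86), and rpusd4, a mitochondrial RNA pseudouridine synthase (-0.86). Their adjusted p lay between 0.0246 and 0.0391. The tRNA methyltransferase gene trmt2a stood at -0.86 (adjusted p = 0.0262). The nuclear receptor gene nr2e3, which directs rod photoreceptor fate, fell by 0.88 (SE 0.14, adjusted p = 0.032).

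In all, 209 of 9301 probe sets passed limma's test with stage as a block, 151 higher and 58 lower. All 209 had the same sign at the 4 stages, which the test nearly requires of a called probe set. At least a 2-fold mean change was reached by 54 of those that were higher and 5 that were lower. Of all kept probe sets, 32.1% had the same sign at 4 stages, against 12.5% by chance, and the stage differences correlated with each other across probe sets at 0.24 to 0.43 (probe sets are not independent). The balance of directions depended on the scaling: centring each array on its median gave 150 higher and 131 lower, and quantile normalization gave 12 and 11. The count was 14 without the 30 hpf arrays and 4 without the 36 hpf arrays, and it was 0 when the groups followed the treatment characteristic, which contradicts the titles at 30 and 36 hpf (84 at an unadjusted p under 0.05). That label leaves no pair at 30 hpf, so those arrays dropped out of its fit. With the level of the brain list as a covariate, 3 of the 209 were left (1056 at an unadjusted p under 0.05). That list was itself higher with ethanol at 30, 36 and 48 hpf, so the covariate overlaps with ethanol and the loss does not show its cause. Without the genes of other-tissue lists there were 251 calls, 199 of them among the 209. That removes listed genes only, and brain markers outside those lists, such as olig3, stayed in. The count was 67 with no filter, and 0 in limma on the 27 and 48 hpf pairs alone (873 at an unadjusted p under 0.05). Both fits with 0 calls had fewer pairs and residual degrees of freedom than the main fit. A 0 there cannot by itself decide between the labels.

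Gene lists fixed beforehand gave 13 that differed as groups by camera, a test that compares a list with all other genes. The genes of mitochondrial respiration lay slightly and evenly lower, with 84 of 86 measured members below 0 and a median of -0.20 (adjusted p = 7.56e-09). No member was called over all genes or adjusted over the list alone. The lowest members were the succinate dehydrogenase assembly factors sdhaf3 (-0.60) and sdhaf2 (-0.47), and ndufa10 of complex I stood at -0.46. Genes of hypoxia and glycolysis lay higher, with 27 of 30 above 0 and a median of 0.25 (adjusted p = 0.00286), and none called over all genes or adjusted over the list alone. Examples were the insulin-like growth factor-binding protein igfbp1a at 1.00 ± 0.40 and the vessel growth factor vegfaa at 0.92 ± 0.27. Genes of p53 and apoptosis had 18 of 20 above 0 and a median of 0.21 (adjusted p = 0.00358). Of these, 2 were called over all genes, namely casp9, the initiator caspase of the mitochondrial death pathway (0.90 ± 0.17, adjusted p = 0.0423), and phlda3, a p53 target (0.59 ± 0.12, adjusted p = 0.0498), and 3 were called adjusted over the list alone. All 3 lists lost the call, each at adjusted p = 0.52 with an estimated correlation, a setting that also uses the few residual degrees of freedom. For p53 and apoptosis the estimated correlation was -0.04, below the preset 0.01, so that loss did not come from a higher correlation.

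Genes of signals that pattern the embryo lay higher too. All 11 measured genes of the Hedgehog pathway were above 0, with a median of 0.52 (adjusted p = 8.46e-05), and 7 were called adjusted over the list alone against 0 over all genes. Among them, foxa2 and nkx2.2a, ventral midline transcription factors, stood at 1.03 ± 0.35 and 1.04 ± 0.42, and the ligand gene shha at 0.89 ± 0.29. All 13 Fgf pathway genes were above 0, with a median of 0.39 (adjusted p = 4.95e-04), 6 called adjusted over the list alone and 0 over all genes, led by the receptor gene fgfr4 at 0.74 ± 0.17. The Wnt pathway had 15 of 20 above 0 and a median of 0.36 (adjusted p = 0.005, 9 adjusted over the list alone, 0 over all genes), with the receptor gene fzd10 at 1.00 ± 0.25. The Notch pathway had 15 of 18 above 0 and a median of 0.32 (adjusted p = 0.01), with 1 higher and 1 lower adjusted over the list alone and 0 over all genes. The ligand gene jag1a stood at 0.72 ± 0.15, while hes6, a factor of neuronal differentiation, stood at -0.54 ± 0.13. These 4 calls were lost, each at adjusted p = 0.52 with an estimated correlation, and those of Wnt and Notch were also lost without the 48 hpf arrays.

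Marker genes of other tissues moved with these groups. Brain genes outside the eye had 21 of 22 above 0 and a median of 0.63 (adjusted p = 1.36e-05), with 2 called over all genes (en1b and en2a) and 7 adjusted over the list alone. The list of optic stalk, ventral eye and periocular genes had 14 of 16 above 0 and a median of 0.32 (adjusted p = 0.00425), with 0 called over all genes, 2 adjusted over the list alone, and the growth factor gene bmp4 at 0.78 ± 0.18. Blood and vessel genes had 17 of 20 above 0 and a median of 0.24 (adjusted p = 0.005). There, mpx, the neutrophil myeloperoxidase (1.39 ± 0.29, adjusted p = 0.0468), plvapb, an endothelial protein (0.81 ± 0.16, adjusted p = 0.0429), and hbbe2, an embryonic globin (0.79 ± 0.13, adjusted p = 0.0307), were called over all genes, and 4 were called adjusted over the list alone. The 3 calls were lost, at adjusted p = 0.52 with an estimated correlation for brain and blood and adjusted p = 0.551 with an estimated correlation for the optic stalk, and the optic stalk call was also lost without the 48 hpf arrays (0.231) and with the upper 30% of probe sets (0.0885).

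Photoreceptor genes were the eye genes that lay lower, with 14 of 17 below 0 and a median of -0.32 (adjusted p = 0.00794), of which only nr2e3 was called, over all genes and adjusted over the list alone. The rod transducin subunit gngt1 stood at -0.61 ± 0.38, the calcium sensor rcvrn2 at -0.58 ± 0.23 and the homeobox gene otx5 at -0.52 ± 0.19. Genes of the cell cycle had 33 of 47 below 0 and a median of -0.15 (adjusted p = 0.0129, and 0.127 under quantile normalization, which ended the call), with none called either way and with cdk2 at -0.51 ± 0.17 and the replication helicase subunit mcm5 at -0.46 ± 0.12. Both calls were lost, at adjusted p = 0.52 with an estimated correlation for photoreceptors and adjusted p = 0.578 for the cell cycle, and the former was also lost without the 48 hpf arrays, the latter without the 30 hpf arrays and with the upper 30% of probe sets (0.0773). Within uncalled lists, some genes passed on their own: vsx1, a bipolar cell factor (-0.75 ± 0.13, adjusted p = 0.032), mafbb, of the Maf family of transcription factors (1.21 ± 0.23, adjusted p = 0.0428), and herpud1, of the unfolded protein response (0.73 ± 0.13, adjusted p = 0.0384). The others were cyp51, of cholesterol synthesis (0.93 ± 0.18, adjusted p = 0.0436), cyp26b1, which degrades retinoic acid (0.84 ± 0.15, adjusted p = 0.0359), the retinol carrier rbp4 (0.78 ± 0.15, adjusted p = 0.0428) and the keratin gene krt1-19e (-0.80 ± 0.14, adjusted p = 0.0352).

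The other 16 lists tested were not called. These were ER stress and unfolded protein genes (-0.04, mean 0.04, adjusted p = 0.905), oxidative stress and Nrf2 genes (-0.02, adjusted p = 0.759), alcohol and aldehyde metabolism (-0.03, adjusted p = 0.644), and immediate early genes (0.11, adjusted p = 0.155). They were also cholesterol synthesis (0.14, adjusted p = 0.15), the retinoic acid pathway (-0.04, mean 0.07, adjusted p = 0.502) and circadian clock genes (0.09, adjusted p = 0.178). Among eye lists, retinal progenitor genes stood at 0.04 (adjusted p = 0.32), retinal ganglion cell and axon genes at 0.20 (adjusted p = 0.13), inner retina interneuron and glia genes at 0.24 (adjusted p = 0.0849), lens membrane, cytoskeleton and regulator genes at 0.17 (adjusted p = 0.18) and pigment cell and RPE genes at -0.09 (adjusted p = 0.374). Muscle genes stood at 0.12 (adjusted p = 0.671), skin and hatching gland genes at 0.05 (adjusted p = 0.538), cartilage, notochord and connective tissue genes at 0.13 (adjusted p = 0.0705) and ribosomal proteins at 0.07 (adjusted p = 0.178). The test of the ER stress and retinoic acid lists pointed up, as their means did, against their medians. Quantile normalization turned the muscle median to -0.06 and gave a test pointing up for the oxidative stress list. Median centring turned the retinal progenitor median to -0.02 and the skin median to -0.01. It also called the inner retina list (adjusted p = 0.0387), and quantile normalization called the cartilage list (adjusted p = 0.0333). Only 4 lens crystallins were measured above the filter, too few for a test, and cryaa, the small heat-shock protein of the lens, stood at -0.19 ± 0.18. With fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, no ethanol list passed, and the lowest adjusted p was 0.0603, for p53 and apoptosis.

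**Figure D2:**
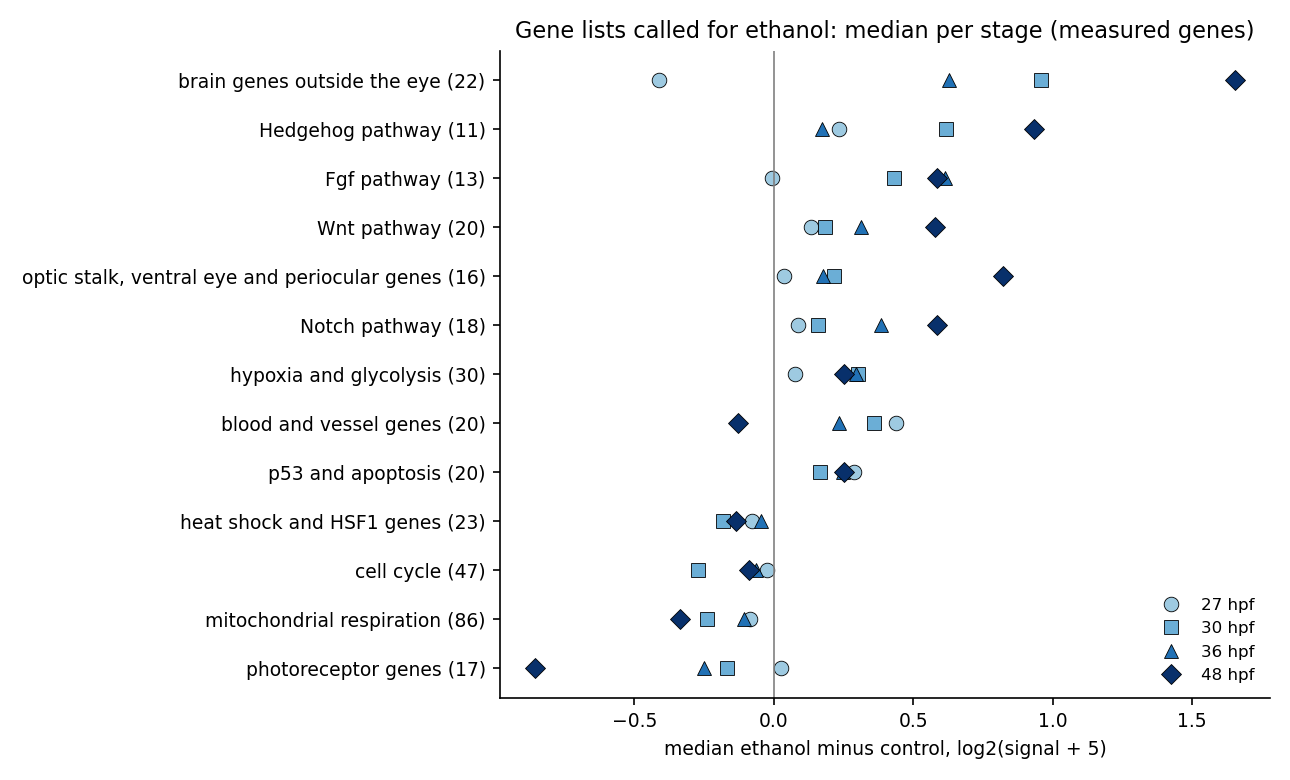
Median difference between the ethanol and the control array, as log2(signal + 5), at each stage for the 13 lists called across stages, with the number of measured genes in brackets. Brain genes run from -0.41 at 27 hpf to 1.65 at 48 hpf and photoreceptor genes reach -0.86 at 48 hpf; under another scaling the sign turns for hypoxia and glycolysis and for photoreceptor genes at 27 hpf, and for the optic stalk list at 27 and 30 hpf.

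The gene hsf1, for the factor named in the study's title, could not be assessed, since its probe set was near background. The list of heat shock and HSF1 genes had 15 of 23 members below 0 and a median of -0.13, with none called over all genes or adjusted over the list alone. Camera called the list lower (adjusted p = 0.0357), but the call was lost at adjusted p = 0.52 with an estimated correlation and at adjusted p = 0.127 under quantile normalization. It was also lost without the 30 hpf (0.189) or the 48 hpf arrays (0.0516) and with the upper 30% of probe sets (0.21). The chaperone gene hsp90aa1.1 stood at -0.49 ± 0.16, the mitochondrial co-chaperonin hspe1 at -0.45 ± 0.13, the Hsp90 activator ahsa1b at -0.44 ± 0.13 and hspa4a, of the Hsp110 family, at -0.44 ± 0.16. Of the heat shock factors alone, only hsf2 was above the filter (-0.32 ± 0.15, adjusted p = 0.221). The hsf1 probe set gave signals of 5.50 to 12 and that of hsf5 1.37 to 8.94, both near background, so their levels could not be compared. The inducible chaperone gene hsp70.3 differed by 0.11 at 27 hpf, -0.85 at 30 hpf, -0.28 at 36 hpf and 1.77 at 48 hpf. Its signal at 48 hpf was 525 in the control and 1806 with ethanol, and its mean change was 0.19 ± 0.35 (adjusted p = 0.779). A brighter probe set shared by 3 hsp70 genes gave 0.08, -0.76, -0.06 and 1.63. In both groups hsp70.3 rose over development, by 4.58 ± 0.52 from 24 to 48 hpf (adjusted p = 7.48e-05).

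The genes that differed most were not the same at each stage. At 27 hpf, after slc16a9b (2.65), the largest increases were ppdpfb, a relative of a pancreatic differentiation factor (signal 72.4 in the control and 351 with ethanol), gcshb (2.11), abat (1.86) and slc1a4, a neutral amino acid transporter (1.57). The largest decreases were in forebrain neuron genes, tbr1b (-1.57) and neurod6b (-1.37), followed by pdcd2l (-1.26), h2ax (439 in the control and 188 with ethanol) and rrp8, of ribosomal RNA processing (-1.17). At 30 hpf, lipoprotein genes made in yolk and liver led, with apobb.1 at 3.77, apoc1 at 3.65, apoa1a at 3.56, the plasma protein gene afp4 at 3.50 and apoa4b.1 at 3.46. The decreases at 30 hpf were mb, which encodes myoglobin (-2.01), h2ax (-1.42), riox2, a nucleolar oxygenase (-1.42), tcnbb, of the vitamin B12 carrier family (-1.40), and atoh7, the proneural gene of retinal ganglion cells (-1.30). At 36 hpf, heart sarcomere genes led, with myl7 at 3.36, tnnt2a at 3.32 and cmlc1 at 2.99. In the 36 hpf control the heart list was dim, with a median log2(signal + 5) of 4.04 against 4.79 for the filter. The size and order of these differences therefore depend on the offset. The gene for the fatty acid importer of mitochondria, cpt1ab, stood at -1.35, and aebp1b, of the extracellular matrix, at -1.52, ahead of rangap1b of nuclear transport (-1.32), msl1b of a chromatin complex (-1.19) and h2ax (-1.12). At 48 hpf, pim2 (3.14), the prostaglandin synthase gene ptgdsb.1 (3.06), slc16a9a (3.02), nkx2.2a (2.98) and the forebrain factor lhx5 (2.98) led. Skeletal muscle genes were lowest, with tnnc2.2 at -3.48, acta1a at -2.80, actc1b at -2.64 and ckma at -2.36, followed by elovl4b, which makes the very long fatty acids of photoreceptors (-2.13).

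The medians of several lists also turned between stages. Brain genes outside the eye had a median of -0.41 at 27 hpf, below all random lists matched on signal, and of 0.96, 0.63 and 1.65 at 30, 36 and 48 hpf, above all of them. Muscle genes stood at 0.20, 0.77, 0.64 and -1.79, with 10 of 13 at least 2-fold lower at 48 hpf. ER stress genes stood at 0.45 at 27 hpf (percentile 100) and at -0.26 at 48 hpf (percentile 4.13), and blood and vessel genes at 0.44 and -0.13 (percentiles 100 and 23.2). Photoreceptor genes reached -0.86 at 48 hpf (percentile 0), with 6 of 17 at least 2-fold lower, while inner retina genes stood at 0.63 (percentile 100), with 10 of 32 at least 2-fold higher. At 30 hpf, retinal ganglion cell and axon genes stood at 0.68 (percentile 100) and cell cycle genes at -0.27 (percentile 0.01). The former list shares eomesa (0.68) with the brain list, while the ganglion cell gene atoh7 was among the largest decreases there. At least 2-fold differences were seen for 103 probe sets at 27 hpf (75 higher, 28 lower), 316 at 30 hpf (285 and 31), 132 at 36 hpf (112 and 20) and 611 at 48 hpf (424 and 187). Neighbouring untreated stages differed at 21 to 476 probe sets, from 24 to 27 hpf and from 36 to 48 hpf. These differences rest on 1 array per group with no replicate check, and percentiles among 10000 random lists only describe these arrays. The median kept probe set of the ethanol array was 0.08, 0.14, 0.00 and 0.02 above that of its control at 27, 30, 36 and 48 hpf, and the values at 30 hpf include that shift of 0.14.

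**Figure D3:**
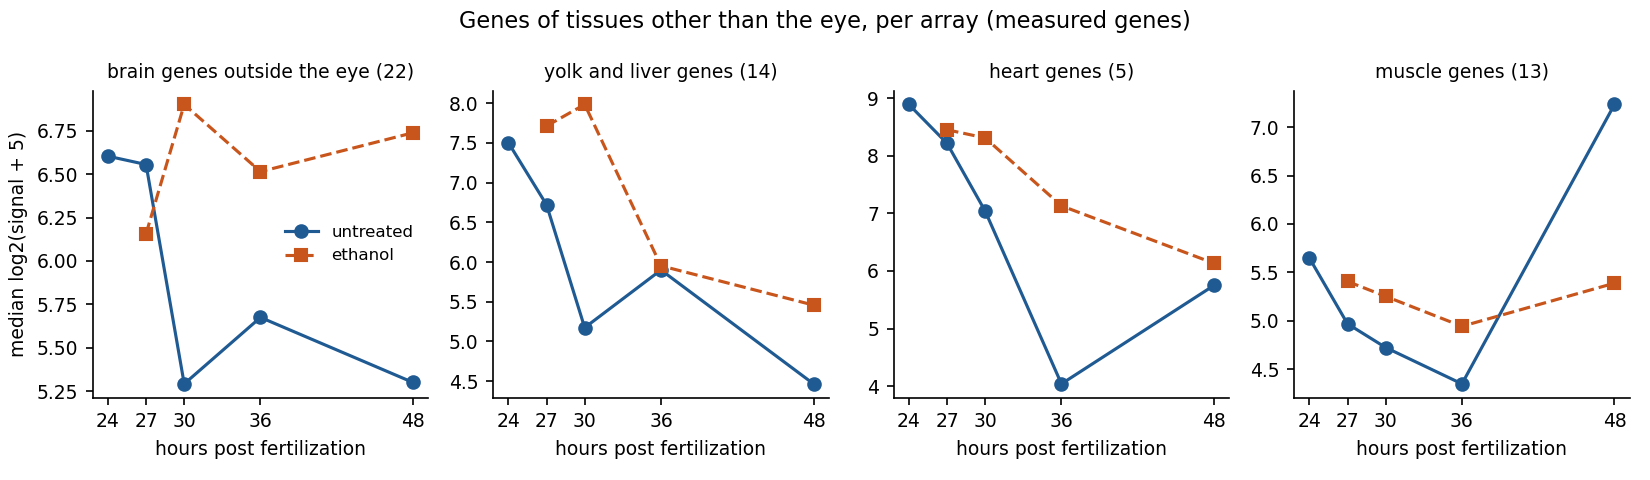
Median log2(signal + 5) of marker lists of brain, yolk and liver, heart and muscle against hours post fertilization, with untreated eyes as circles and ethanol-exposed eyes as squares, 1 array per point. Untreated arrays jump as well: the heart list (5 genes) of the 36 hpf control lies 2.68 below the line through its neighbours (-2.68), and muscle rises more from 36 to 48 hpf in the controls (4.35 to 7.23) than in the ethanol arrays (4.94 to 5.39).

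Over development, from 24 to 48 hpf, several genes of photoreceptors and of the lens were among those that rose most. The steepest rise was in six7, a cone photoreceptor transcription factor (6.32 ± 0.73, adjusted p = 8.6e-05). The lens gene lctla rose by 5.78 ± 0.76, ndrg1b, of the stress-responsive Ndrg family, rose by 5.63 ± 0.47, and crx, the homeobox regulator of photoreceptor genes, rose by 5.53 ± 0.58. They were followed by rcvrn2 (5.21 ± 0.34), the phospholipase plaat1 (5.13), pcp4l1, of a family of calmodulin-binding peptides (4.95), cryaa (4.86), the lens filament gene bfsp2 (4.85) and the cone transducin subunit gngt2a (4.76 ± 0.25, adjusted p = 2.7e-06). The steepest falls included genes of tissues beside the eye, whose marker lists also jumped between untreated arrays (from the line through their neighbours, heart -2.68 at 36 hpf, yolk and liver -1.58 at 30 hpf). These were afp4 (-3.81 ± 0.63), the heart genes cmlc1 (-3.77), myl7 (-3.25) and tnnt2a (-3.10), the transferrin gene tfa (-3.44), apoa4b.1 (-2.73) and fetub (-2.58). The Wnt antagonist sfrp5, a gene of the early optic vesicle and forebrain, fell by 3.55, the keratin krt1-19d fell by 2.79 and the transglutaminase tgm1l4 fell by 2.64.

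**Figure D4:**
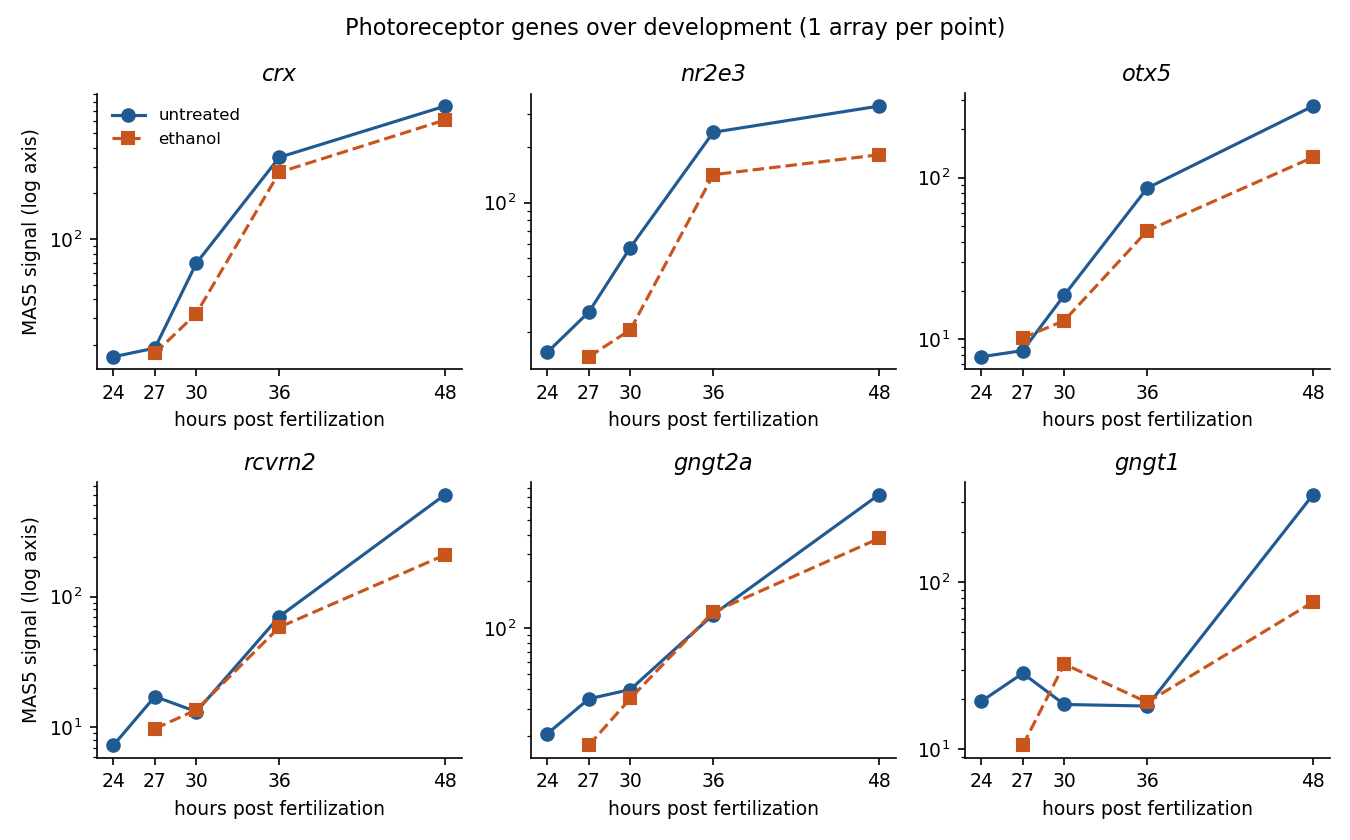
MAS5 signal (log axis) of 6 photoreceptor genes against hours post fertilization, with untreated eyes as circles and ethanol-exposed eyes as squares, 1 array per point. All 6 rise toward 48 hpf in both groups; nr2e3 is lower with ethanol at all 4 stages, while rcvrn2 and gngt1 part from the control mainly at 48 hpf (-1.51 and -2.06).

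Photoreceptor genes had 13 of 17 members rising and none falling, with a median of 2.80 (adjusted p = 1.05e-08). This call was lost at adjusted p = 0.115 with an estimated correlation, as were the other 13 of this comparison, whose second p in brackets is the one with an estimated correlation. Inner retina interneuron and glia genes had 20 of 32 rising and 2 falling (median 1.66, adjusted p = 6.42e-07 and 0.146), among them ptf1a, which specifies amacrine and horizontal cells (4.44), and vsx1 (4.07). Retinal ganglion cell and axon genes had 9 of 17 rising (1.18, adjusted p = 5.15e-06 and 0.208), led by isl1a (2.98), and hypoxia and glycolysis genes 15 of 30 (1.07, adjusted p = 2.2e-07 and 0.107), led by ndrg1b and ndrg1a (3.03). Lens membrane, cytoskeleton and regulator genes had 5 of 11 rising (0.80, adjusted p = 0.00299 and 0.146), with prox1a at 3.45, and cartilage and connective tissue genes 4 of 22 (0.66, adjusted p = 5.22e-06 and 0.107), with the collagens col2a1a (3.34) and col9a3 (2.78). The p53 and apoptosis list had 7 of 20 rising (0.60, adjusted p = 0.00294 and 0.107), with gadd45aa at 2.36, and retinal progenitor genes 5 of 27 (0.39, adjusted p = 0.00104 and 0.292), of which six7 and vsx1 also mark differentiating cells. Muscle genes had 4 rising and 1 falling of 13 (1.2, adjusted p = 0.0349 and 0.626), skin and hatching gland genes 7 and 2 of 39 (0.18, adjusted p = 0.0163 and 0.292), clock genes 2 rising of 14 (0.68, adjusted p = 0.0445 and 0.269), and ribosomal proteins none of 76 (0.30, adjusted p = 2.22e-05 and 0.626). Cell cycle genes had 16 of 47 falling and none rising (-0.62, adjusted p = 2.52e-06 and 0.504), with the replication inhibitor gmnn at -2.11 and the helicase subunits mcm3 at -1.78 and mcm2 at -1.70. Alcohol and aldehyde metabolism genes had 1 of 16 falling, aldh4a1 of proline breakdown at -1.67 (median -0.66, adjusted p = 0.0349 and 0.269). Each of these counts was the same adjusted over the list alone, except for hypoxia and glycolysis (16 rising) and muscle (6 rising). The pigment cell list was not called (0.43, adjusted p = 0.0795), although rpe65a, of the visual cycle, rose by 3.53.

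Of 9301 probe sets, 1531 changed at least 2-fold with an adjusted p under the threshold, 844 rising and 687 falling, in limma's fit of log2 signal on hpf over 9 arrays. Of the 14 lists, fry called all but muscle and ribosomal proteins, with adjusted p from 2.17e-04 to 0.00907 among the other 12. Medians and means had opposite signs for heat shock genes (-0.08 and 0.11) and Notch genes (0.22 and -0.02), neither of them called. Without the 48 hpf arrays the muscle list turned to -1.36 and the clock list to -0.01, and the calls of cell cycle (adjusted p = 0.875), ribosomal protein (0.0711), skin (0.119) and alcohol metabolism genes (0.53) were lost. Without the 30 hpf arrays those of clock (0.0681) and alcohol metabolism genes (0.0504) were lost. The clock call was also lost with no filter (median 0.26, adjusted p = 0.24), a 4 times larger offset (0.054) and the upper 30% of probe sets (0.473). The upper 30% also ended the calls of the alcohol metabolism, lens membrane and p53 lists (each 0.141). No filter ended that of skin genes (0.0665), no offset that of muscle genes (0.0743), and quantile normalization that of ribosomal proteins (median -0.02, adjusted p = 0.649).

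The change of the ethanol difference with stage was tested as an interaction, given as the extra log2 change from 24 to 48 hpf in ethanol-exposed eyes. The ventral neural tube factor nkx2.2a gained 3.39 ± 0.40 (adjusted p = 0.0293), the kinase gene pim2 gained 2.69 ± 0.35 (adjusted p = 0.0313), the acute phase transcription factor cebpb gained 3.11 ± 0.46 (adjusted p = 0.0366) and the prostaglandin synthase ptgs2a gained 2.79 ± 0.42 (adjusted p = 0.0366). The gene tmem69, of a membrane protein, lost ground at -2.60 ± 0.32 (adjusted p = 0.0293). Brain genes had 20 of 22 members above 0 and a median of 1.64 (adjusted p = 1.42e-13), with 14 called adjusted over the list alone and 0 over all genes. The call was lost at adjusted p = 0.237 with an estimated correlation. Muscle genes had 10 of 13 below 0 and a median of -2.18 (adjusted p = 0.00521, lost at 0.514 with an estimated correlation). ER stress genes had 16 of 21 below 0 and a median of -0.68 (adjusted p = 1.48e-04, lost at 0.197 with an estimated correlation), with 10 adjusted over the list alone and 0 over all genes, among them the protein disulfide isomerases pdia6 (-1.46) and pdia4 (-1.23). Hedgehog genes stood at 0.71 (adjusted p = 2.36e-06, 3 adjusted over the list alone, 1 over all genes), optic stalk genes at 0.81 (adjusted p = 8.05e-08) and photoreceptor genes at -0.63 (adjusted p = 0.0291). These 3 calls were lost at adjusted p = 0.237, 0.237 and 0.340 with an estimated correlation. The photoreceptor call was also lost under quantile normalization (0.0918), and those of Hedgehog (median 0.01, adjusted p = 0.566) and the optic stalk list (0.17, 0.29) without the 48 hpf arrays.

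In limma's fit over 9 arrays, 11 probe sets passed, 7 upward and 4 downward. At an unadjusted p under 0.05 there were 1178. Camera called 17 lists, none of which kept its call, with adjusted p from 0.197 to 0.627 with an estimated correlation, and fry called ER stress alone (adjusted p = 0.0175). The count was 0 without the 24, 27, 30 or 48 hpf arrays, and without the 48 hpf arrays the muscle list turned to 0.71 and the photoreceptor list stood at -0.27, with a test pointing up.

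Ethanol-exposed eyes were placed earlier than their age on the developmental path of the controls, while the correlation of the ethanol difference with the slope of the controls ran the opposite way. Placed by the 500 probe sets that varied most among the controls, the 27 hpf array lay at 24.8 hpf, the 30 hpf array at 27.7, the 36 hpf array at 34.8 and the 48 hpf array at 43.5. The controls at 27, 30 and 36 hpf, placed on the path of the other controls, were off by -1.66, 0.54 and 1.35 hours, a root mean square error of 1.27 hours. The shifts of the ethanol arrays were -2.18, -2.33, -1.19 and -4.51 hours, of which the one at 36 hpf was within that error. At 27 hpf the control was also placed early (-1.66 hours), so the shift of -2.18 hours there is not clearly beyond the error. No control could be placed at the 48 hpf end, so the error of the shift of -4.51 hours is unknown. The 36 hpf array moved to 37.4 hpf with 2000 probe sets on the path. The 30 hpf array was the least stable, at 25.2 hpf with a 4 times larger offset, 25.6 with quantile normalization, 25.8 with no filter, 24.3 with the upper 30% of probe sets and 26.4 with 200 on the path. With no filter the 48 hpf array lay at 42.2 hpf, and by the treatment characteristic the 27 and 48 hpf arrays lay at 28.7 and 42.0 hpf. Without the genes of other-tissue lists, some of which jump between untreated arrays, the 4 arrays lay at 25.0, 28.3, 35.2 and 44.4 hpf. Across probe sets, the ethanol difference correlated at 0.18, 0.12, 0.06 and 0.03 with the slope of the controls of the other stages, a mean of 0.10. All 4 were positive, so genes that rise in the controls tended to be higher with ethanol, whereas a lag in development would make them lower. The exact two-sided permutation p was 0.125, the smallest that 4 stages allow.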

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

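Of the tests below, only the 35 splits of the arrays were written before the result was seen. The choice of the 8 comparable splits and all other tests came after it. What marked each result was a test of whether the ethanol difference changed with stage. It marked the 11 probe sets called for the interaction, with nkx2.2a at 3.39, cebpb at 3.11, ptgs2a at 2.79, pim2 at 2.69 and tmem69 at -2.60 (log2 over 24 hours). It also marked 17 gene lists, none called with an estimated correlation, whose ethanol difference moved upward with stage for brain genes (1.64), the optic stalk list (0.805), Hedgehog (0.71), Notch (0.51), Wnt (0.40) and Fgf (0.39) genes. It moved upward as well for retinal progenitor (0.37), inner retina (0.36), lens membrane (0.26), ribosomal protein (0.24), hypoxia and glycolysis (0.20) and immediate early (0.14) genes. It moved downward for muscle (-2.18), ER stress (-0.68), photoreceptor (-0.63), oxidative stress (-0.40) and mitochondrial respiration (-0.27) genes. Calls were also lost without the 48 hpf arrays for Hedgehog, optic stalk, lens membrane, oxidative stress, mitochondrial and immediate early genes, and without the 27 hpf arrays for Wnt, Fgf, hypoxia and immediate early genes. Quantile normalization ended those of photoreceptor and ribosomal protein genes, and median centring that of immediate early genes. For the interaction, 4 of 35 splits of the 8 arrays gave at least 11 called probe sets, with 141 as the highest other value. The splits with 141 and 34 calls part all 4 pairs, as the real grouping does, and the one with 23 calls parts 2. Those that part all 4 differ from the real grouping only in which array of some pairs is labelled ethanol. An ethanol difference shared by the stages then changes sign between stages and can itself be called as an interaction. Such splits still hold the ethanol difference, so the count cannot decide whether chance gave the 11 calls. Chance was not excluded.

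For the ethanol effect itself, stage was a block, so only the 8 splits that part all 4 pairs are fits of the same form. These are too few for a share under 0.05. The real grouping was the only 1 of the 8 with as many as 209 called probe sets, with 0 as the highest other value, and 3 of the 8 gave at least the 13 called lists, with 16 as the highest other value. Of the remaining splits, 24 part 2 pairs and hold less information, and 3 part none and could not be fitted. Of 33 probe sets chosen for at least a 2-fold change in the same direction at 27 and 48 hpf, 84.8% kept that direction at 36 hpf and 90.9% at 30 hpf. The share at 36 hpf goes against exchanged arrays there. Its 95% interval (68.1 to 94.9) treats the probe sets as independent. They are not and come from 1 pair of arrays, so the interval is too narrow.

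Other tissue left on the dissected eyes was weighed for the brain, heart, yolk and muscle genes. The heart list (5 genes) of the 36 hpf control lay 2.68 below the line through its neighbours (-2.68). If that array's title is right, ethanol cannot cause such a jump, which fits uneven dissection. The treatment characteristic marks that array as ethanol, so the jump does not settle the cause. The 30 hpf control is untreated by both labels. From the line through its neighbours it lay at -1.58 for yolk and liver, -1.29 for midbrain and -0.65 for hindbrain genes. That line uses the disputed 36 hpf control, but both 36 hpf arrays lay higher in the yolk and liver list (5.9 and 5.95 against 5.17). Part of the differences at 30 hpf in these lists may therefore come from a low control, which rests on that array alone. For brain genes, 9 of 9 medians of forebrain, midbrain and hindbrain genes at 30, 36 and 48 hpf were above 0, while at 27 hpf they were -0.55, 0.29 and 0.39. These lists had 15, 3 and 3 measured genes, so the midbrain and hindbrain medians rest on few genes. The region lists were written after the values were seen and hold the called genes en1b, en2a and olig3, so more brain left on the eyes and an ethanol effect on brain genes cannot be told apart. Signals shared by brain and eye, such as the Hedgehog, Wnt and Fgf genes, could follow from the same tissue.

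The lower photoreceptor genes at 48 hpf (-0.86) were weighed against dilution and against later development. Lens crystallin and pigment cell genes (17 genes, of which 4 were crystallins) had a median of -0.11, a difference of 0.75 (95% interval -0.04 to 1.08). Dilution would lower them equally only if the other tissue did not express them. The pigment cell list holds genes that other tissue may express, such as bhmt, so this comparison does not measure dilution alone. Other eye lists were higher at 48 hpf, inner retina at 0.63, lens membrane at 0.39 and retinal progenitor at 0.24, which goes against dilution as the whole cause unless brain tissue that shares some of their genes raised them, so dilution and a photoreceptor effect cannot be told apart. With the photoreceptor genes taken out, the array lay at 43.6 hpf, and a straight line between the 36 and 48 hpf controls predicts 47.5% of the observed median (33.7 to 61.3). That share rests on the straight line and on an error not measured at the 48 hpf end, and its bound was rewritten after the value was seen, so a delay as the whole cause or as a part cannot be told apart.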

How the results depend on the processing

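Counts, list counts and placements were recomputed under the alternatives chosen for each, not under every one. Of these values, 132 stayed within the limits set and 54 moved. Of the single genes and lists, 772 values kept their direction and side of the threshold, 239 kept only the direction (106 lists, 133 genes) and 7 reversed. Every alternative chosen in advance was run. What caused each move was not tested. Dim probe sets, near the MAS5 background, limit what can be measured.

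With no offset, the interaction gave 7 calls. An offset 4 times larger gave 327 calls for ethanol, 23 for the interaction, 43, 161 and 72 differences at 27, 30 and 36 hpf, and an apparent 25.2 hpf for the 30 hpf ethanol array. Quantile normalization gave 23, 17 and 25.6 hpf for the ethanol, interaction and 30 hpf values, with all 23 among the 209. No filter gave 67 and 0, and 25.8 and 42.2 hpf for the 30 and 48 hpf arrays. The upper 30% gave 624 for development, 31, 85, 41 and 217 differences at the 4 stages, 24.3 hpf for the 30 hpf array and 9 development lists. The treatment characteristic as label gave 0 and 0, 28.7 and 42.0 hpf for the 27 and 48 hpf arrays, 6 ethanol lists and an Fgf median of 0.0421 with the test reversed. Its ethanol fit had no pair at 30 hpf and left those arrays out. The 27 and 48 hpf pairs alone gave 0 calls for ethanol in limma (873 at an unadjusted p under 0.05) and 123 for the interaction. Both of these fits had fewer residual degrees of freedom than the main ones.

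For ethanol, linear hpf gave 498, no stage term 7, limma-trend 437, and robust variances 201. For the interaction, log2 of hpf gave 5 and 8 arrays gave 0. An estimated correlation left 0 ethanol, 0 development and 0 interaction lists. With 200 probe sets on the path the 30 hpf array lay at 26.4 hpf, and with 2000 the 36 hpf array lay at 37.4 hpf. A 1.5-fold threshold gave 875, 1344, 881 and 1972 differences at the 4 stages, and a 3-fold threshold 9, 53, 21 and 165.

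Leaving out each stage in turn gave 4 to 182 calls for ethanol, 1298 to 1631 for development and 0 to 12 for the interaction, and 9 to 15, 12 to 17 and 10 to 17 called lists. The ranges were -0.34 to 0.54 for hsp70.3 with ethanol, -1.36 to 1.27 for muscle and -0.00862 to 0.75 for clock genes over development, and -3.07 to 0.71 for muscle and -0.84 to -0.27 for photoreceptor genes in the interaction. In each, the end nearer the other direction came without 48 hpf, where the photoreceptor test turned relative to other genes. Among alternatives chosen after seeing the data, the brain list as a covariate left 3 ethanol calls (1056 at an unadjusted p under 0.05) and turned hsp70.3 to -0.18, and leaving out the genes of other-tissue lists gave 251.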

Other observations

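Genes of the nucleolus and of ribosome assembly were read in a list written after the values were seen. Of 70 measured genes, 67 were below 0, with a median of -0.36 (camera adjusted p = 2.87e-17, lost with an estimated correlation at 0.254), and medians of -0.57, -0.48, -0.32 and -0.14 at 27, 30, 36 and 48 hpf. The called members included surf6 (-0.97 ± 0.14), polr1c, a shared subunit of RNA polymerases I and III (-0.79 ± 0.13), wdr4, of tRNA methylation (-0.77 ± 0.15), nip7, of ribosome assembly (-0.70 ± 0.14), tsr1, of small subunit maturation (-0.68 ± 0.13), and wdr74 (-0.60 ± 0.12). These genes fell over development, with a median of -1.18 and 70 of 70 below 0, so a delay alone would be expected to raise them with ethanol. Without the 7 called members the median of the other 63 was -0.35 (camera adjusted p = 5.90e-14, lost with an estimated correlation at 0.254). Because the list was written after the values were seen, this leaves open whether the whole set was lower.

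Glycine cleavage and inflammation genes were read in lists of the same kind. With gcshb, the gene gldc, for the P protein of glycine cleavage, was higher by 1.28 ± 0.17 (adjusted p = 0.0246), while the paralog gcsha stood at -0.32 ± 0.12 (adjusted p = 0.165). The 20 genes of glycine, serine and one-carbon metabolism had a median of 0.17 (camera adjusted p = 0.00625, lost with an estimated correlation at 0.254), with 7 below 0. The list holds the called genes abat, gcshb and gldc, so its p-value partly restates values already seen. It was not tested without them. The medians were 0.41, 0.06, -0.04 and 0.42 at 27, 30, 36 and 48 hpf. The 20 genes of inflammation and acute stress had a median of 0.41 (camera adjusted p = 0.00625, lost with an estimated correlation at 0.254), with 6 below 0. This list too holds called genes, mpx and pim2. Its medians were 0.26, 0.04, 0.31 and 0.90 at 27, 30, 36 and 48 hpf. Quantile normalization turned that at 30 hpf to -0.09 and median centring to -0.10. Among the higher members at 48 hpf were mcl1b at 2.72, mpx at 2.71, cebpb at 2.55, ptgs2a at 2.35 and atf3 at 1.85.

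Yolk and liver genes (14 measured) differed by medians of 0.79, 2.95, 0.14 and 0.76 at the 4 stages, and heart genes (5 measured) by 0.26, 1.17, 2.99 and 0.69. Among untreated arrays, the yolk and liver list of the 30 hpf control lay at -1.58 from the line through its neighbours and the muscle list of the 36 hpf control at -1.16.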
